A study of Homo sapiens with 6 samples.

How the data were processed

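Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase cuts open DNA and inserts sequencing adapters, in MCF-7 cells. MCF-7 is a human breast adenocarcinoma line that carries the estrogen receptor. Cells were treated for 24 h with the solvent DMSO, with GDC9545 at 300 nM or with GNE858 at 300 nM, and each of the 3 groups has 2 libraries, 6 in all. Per the labels' protocols, the cells were detached, frozen, shipped, thawed and tagmented with Nextera enzyme. The labels do not say whether the 2 libraries of a group come from separate cultures. The p-value of a single region therefore measures the spread between these samples, which may be technical only. P-values for sets of genes or of regions compare genes or regions, which are not replicates.

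The authors deposited 1 list of peaks per library, on hg38, so peaks were called per library and not on pooled samples. The submitters' processing notes name cutadapt 1.9.1, Bowtie2 2.2.6 and MACS2 2.1.0, with no settings. The file names mark duplicate reads and mitochondrial reads as removed, a Tn5 offset, a caller threshold of p 0.01, a limit on the number of peaks and a filter of excluded regions, and they mark the reads of GNE858 replicate 1 alone as trimmed. Each line of the deposited lists holds an interval, its summit, the fold enrichment over background (a ratio), the −log10 p and the −log10 q of the authors' caller. The smallest −log10 p in any list was between 2.00056 and 2.0035, at the stated threshold. None of these values is normalised between libraries: at a deeper library the same accessibility gives a larger −log10 p, and background sets the fold.

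Depth is not stated. It was read from the values, because the caller's fold enrichment is (pileup + 1) / (background + 1) and its −log10 p is a Poisson tail of the same pair. For every summit the whole pileup and the background were solved from these 2 deposited columns, and 100% of the summits in each library gave a whole pileup whose −log10 p matched the deposited one within 0.01. The largest mismatch in any library was 0.00527746. A pileup is the number of Tn5 cut sites in 150 bp around a summit, the smallest peak width. The lowest background found in a library, which between 31.2% and 38.4% of its summits share, gave its depth: 3.26 and 2.50 cut sites per 150 bp in DMSO replicates 1 and 2, 1.83 and 2.19 in GDC9545 replicates 1 and 2, and 3.17 and 3.09 in GNE858 replicates 1 and 2. The other summits carry a higher local background, in steps of a 10 kb width. Depth and group were therefore not balanced, with both GDC9545 libraries the shallowest. Counting error alone is about the square root of a pileup, so a pileup of 23, the median in GDC9545 replicate 1, is less exact than the 34 of GNE858 replicate 1.

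Regions were non-overlapping windows of 250 bp on each side of a summit, taken from the strongest summit down over all 6 libraries, from peaks with a q of 0.01 or less. This gave 288152 regions. A region was called in a library when such a summit lay inside it. A region was lost in a comparison when both reference libraries called it and no deposited peak touched it in either treated library, and gained in the mirror case. No test of presence was planned with 2 libraries per group, and the counts were set beside the 4 cross-group patterns, in which 1 library of each group called the region and the other 2 did not touch it. They were also set beside 20 simulations of libraries without any treatment effect, drawn at the real depths. A first version of that simulation took its dispersion from strong regions (0.00808) and gave far fewer cross-group patterns than the data, so the dispersion was recalibrated to 0.462 to give the observed mean of those patterns.

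The comparison of levels fixed before the data were examined was a rank test. In the 109084 regions with a summit in all 6 libraries, the fold enrichment of the highest summit was turned into normal scores of its rank within the library, and limma 3.58.1 (R 4.3.3) fitted the 3 groups over all 6 libraries. An adjusted p (Benjamini-Hochberg) under 0.05 was a call. The simulation of this test ranked pileups, and ranks of fold enrichment were not simulated. With ranks of simulated pileups, limma recovered 0 of 100 regions changed by 2-fold and 0 of 100 changed by 4-fold in every comparison. After that result was seen, a second test was added: limma with voom weights on the recovered whole pileups, scaled by the median ratio over the shared regions (called the pileup test here). On simulated data it recovered 45, 56 and 48 of 100 regions changed by 2-fold and 97, 98 and 92 of 100 changed by 4-fold for GDC9545 against DMSO, GNE858 against DMSO and GNE858 against GDC9545, with 10, 16 and 8 false calls among 109084 regions. Both tests are reported. A log2 fold change from the pileup test is relative to the median shared region, and regions without a summit in some library are not in it. The rule for lost regions recovered 19, 24 and 16 of 100 regions that fell 4-fold and 45, 63 and 56 of 100 that fell 16-fold in the same order of comparisons.

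Regions were assigned to protein-coding genes of RefSeq's GRCh38.p14 annotation. A region within 1 kb of a gene's start or end went to the gene with the nearest end, even inside another gene. Other regions went to the gene whose body holds the window centre, or else to the nearest one within 50 kb. This gave 230736 regions a gene. The annotation at hand has gene starts and ends without strand, exons or transcripts. Promoters, as planned, were therefore replaced by gene ends, within 1 kb of either end of a gene, and other regions are in a gene body or intergenic. The planned assignment to the nearest transcription start within 50 kb was likewise replaced by the rule above. Assignment by distance does not show which gene a region acts on. The 18 gene lists were written before the data were examined: estrogen-induced, estrogen-repressed, luminal epithelial, basal and myoepithelial, mesenchymal, cell cycle, growth arrest, AP-1 and immediate early, interferon, apoptosis, cholesterol and fatty acid, unfolded protein response, growth factor receptor, other steroid receptor and response, and housekeeping genes, with markers of immune cells, hepatocytes and neurons. Lists were tested with limma's camera on the mean over a gene's regions, with a preset correlation of 0.01 and beside it an estimated one, and lost and gained regions with 10000 random gene sets matched on the number of regions. Tested on simulated data, camera called 4 of 50 random lists and the changed one, and the random gene sets called 1 of 20 random lists and the changed one. Shares of gene ends among lost and gained regions were compared with cross-group regions by Fisher's exact test, two-sided.

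Regions were named by a rule fixed beforehand: ESR1, GREB1, TFF1, PGR, FOXA1, GATA3, CCND1 and MYC always; the 8 lost and 8 gained regions with a gene that had the highest mean percentile of −log10 p; the 8 regions per direction with the smallest adjusted p whose groups do not overlap; and up to 4 members of each list, 8 for the estrogen-induced list. For GNE858 against GDC9545 the numbers were 4. The part of the rule written for the rank test was applied to the pileup test, a choice made after seeing the data. Alternatives were other call thresholds, the 50000 strongest peaks of each library, merged intervals, 50% cover of the window, other ranks and filters, the replicate number as a block, leaving out each library in turn, and, chosen after seeing the data, libraries thinned to the background depth of the shallowest, scaling by background depth and limma without weights. Sequence motifs were planned and not run, as no genome sequence was used here. Tables were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures with matplotlib 3.10.9.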

Results

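Open chromatin was mapped in MCF-7 breast cancer cells after 24 h with DMSO, with GDC9545 or with GNE858, each compound at 300 nM. GDC9545 is giredestrant, an oral antagonist and degrader of the estrogen receptor. GNE858 is known here by its code name only. The series asks how each compound changes accessibility relative to DMSO, and with both compounds at the same dose and time they can also be compared with each other. Each group had 2 libraries.

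Peak lists held 242065 and 221000 summits in DMSO replicates 1 and 2, 200126 and 219555 with GDC9545, and 240625 and 277029 with GNE858. The depth behind them, as background cut sites per 150 bp, was 2.88 ± 0.534 in DMSO, 2.01 ± 0.259 with GDC9545 and 3.13 ± 0.0590 with GNE858 (mean ± SD, n = 2 each). GNE858 replicate 2 had the most summits and the weakest ones, with a median pileup 7.12 times background against 10.7 times in GNE858 replicate 1 and at least 9.82 times in the other libraries. An exact permutation test of 2 against 2 libraries cannot give a p below 0.333, so none was run on these values. Across the 109084 regions with a summit in every library, the log2 pileups of the 2 GDC9545 libraries correlated at r = 0.960, and the first principal component, with 35.0% of the variance, set both GDC9545 libraries (83.9 and 74.9) apart from the DMSO (−49.8 and −47.2) and GNE858 libraries (−27.9 and −33.9). These correlations are across regions, which are not independent replicates.

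By the pileup test, added after the planned one, accessibility was lower with GDC9545 at genes that estrogen is known to induce. By the planned ranks, camera did not call these genes (adjusted p = 0.613), with 28 lower and 19 higher. In the pileup test, 75 of the 435 shared regions assigned to the 47 genes of the estrogen-induced list fell and 1 rose, so that 38 genes had at least 1 lowered region (105 and 2 regions adjusted over the list alone). Over all shared regions 2.63% fell, against 17.2% of those of this list. GREB1, an estrogen-responsive gene linked to growth of breast cancer cells, carried the clearest group of changes, with 8 of its 22 shared regions lower. At one of them, on chromosome 2 from 11530906 to 11531405 (hg38, gene body), the scaled pileup was 369 ± 6.21 in DMSO and 81.3 ± 2.40 with GDC9545 (mean ± SD, n = 2 each), a log2 fold change of −2.17 (SE 0.18, limma adjusted p = 1.26e-11).

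Other estrogen-induced genes had regions that fell with GDC9545. The region near PDZK1, a scaffold protein gene, on chromosome 1 from 145708093 to 145708592 (gene end) fell by a log2 change of −2.41 (SE 0.26, limma adjusted p = 2.15e-08). At HSPB8, a small heat shock protein gene, the region on chromosome 12 from 119171175 to 119171674, 7506 bp outside the gene, went from 77.8 ± 3.42 to 14.2 ± 4.98 (−2.47, adjusted p = 2.35e-06). Log2 changes were −1.72 at ELOVL2, a fatty acid elongase, −1.39 at the potassium channel gene KCNK5, −1.36 at the small GTPase RAB31, −1.16 at the ADP-ribosyltransferase TIPARP and −1.12 at BCL2, an inhibitor of apoptosis, with adjusted p from 0.000342 to 0.0237. The list as a whole fell by limma's camera (adjusted p = 3.08e-15), with a median gene shift of −0.29 on the log2 scale. With an estimated correlation camera's adjusted p was 0.0387, and 0.191 with the replicate number as a block as well. That correlation was −0.0168 in the 6-library pileup fit, which all 3 comparisons share. It lay under the preset 0.01 and so does not account for the larger p. The median gene shift was −0.277 to −0.305 when any 1 of the 6 libraries was left out. The count of 75 rested on both GDC9545 libraries, as it was 32 without replicate 1 and 29 without replicate 2, and it was 27 when libraries were scaled by background depth.

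The genes followed in every comparison divided into those with lowered regions and those without. TFF1, a secreted protein and a classic estrogen target, had 2 of 4 shared regions lower with GDC9545, and the one in its gene body on chromosome 21 from 42364390 to 42364889 went from 146 ± 1.40 to 85.8 ± 9.99 (log2 −0.78, SE 0.19, limma adjusted p = 0.0109). PGR, the progesterone receptor gene, had 1 of 3 lower, at its end on chromosome 11 from 101129558 to 101130057 (154 ± 13.5 to 94.8 ± 2.80, log2 −0.68, adjusted p = 0.0279). ESR1, which encodes the estrogen receptor, had 2 of 32 lower, among them the region in its body on chromosome 6 from 151666395 to 151666894 (181 ± 21.4 to 104 ± 22.5, log2 −0.78, adjusted p = 0.00627). CCND1, which encodes cyclin D1, had 3 of 8 lower, with −0.61 at the region on chromosome 11 from 69654592 to 69655091 (gene end, adjusted p = 0.000133). MYC had 3 of 14 lower and 1 higher, with −1.12 on chromosome 8 from 127742931 to 127743430 (gene end, adjusted p = 0.00109). None of the 5 regions of FOXA1 and none of the 15 of GATA3, which encode transcription factors of luminal cells, passed the test. Their smallest adjusted p values were 0.503 and 0.114.

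**Figure D1:**
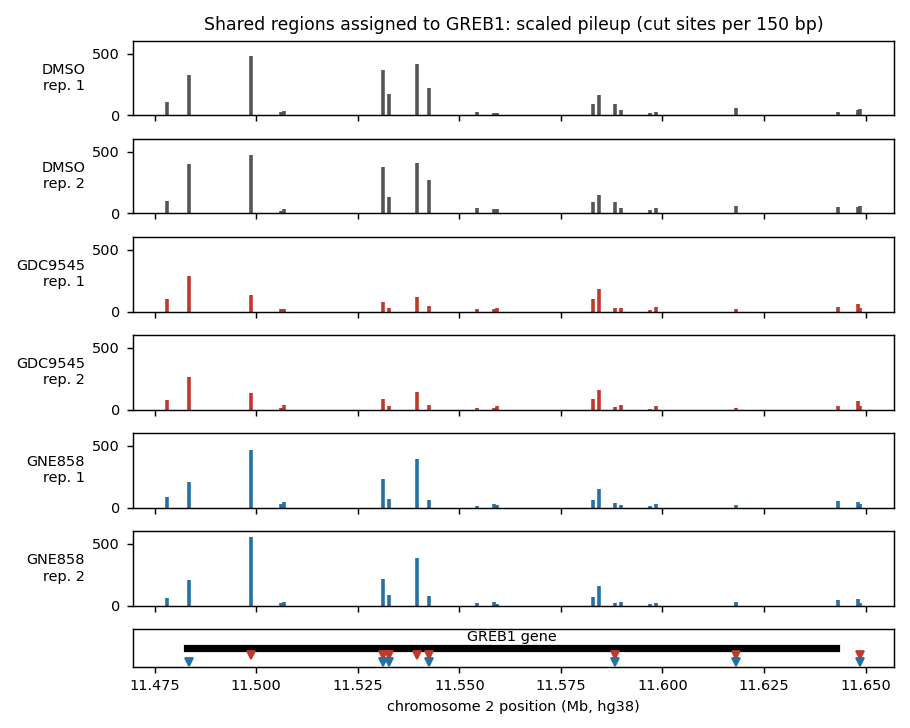
Scaled pileup (cut sites per 150 bp, vertical axis) of the 22 shared regions assigned to GREB1 along chromosome 2 (Mb, hg38), 1 track per library, with the gene as a bar and triangles under regions called lower in the pileup test (red GDC9545, blue GNE858). The region starting at 11530906 fell with both compounds, and the one starting at 11498496 was at 477 in DMSO, 135 with GDC9545 and 513 with GNE858 on average.

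Over all genes, 2870 regions fell and 1507 rose with GDC9545 in the pileup test. Chromosome 20 had the highest share of called regions, 6.26%, against 3.63% on chromosome 1, and several of the regions with the smallest adjusted p lay on it. Near PARD6B, a cell polarity gene, the region on chromosome 20 from 50724778 to 50725277 (6552 bp outside the gene) fell from 1429 ± 85.6 to 439 ± 62.7 (log2 −1.72, SE 0.10, limma adjusted p = 6.84e-16). A region with no gene within 50 kb, on chromosome 20 from 48076127 to 48076626, fell by a log2 change of −1.82 (SE 0.11). The other lowered regions among the 8 with the smallest adjusted p were at or near SARS1 (−2.12), MLPH (−2.15), RHOD (−2.35), TMEM229B (−2.52), ADCY9 (−1.97) and NINL (−1.77). MLPH encodes melanophilin, RHOD a small GTPase and ADCY9 an adenylate cyclase.

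The 8 raised regions with the smallest adjusted p were all on chromosome 20. Regions with high pileups have smaller errors, so a ranking by adjusted p favours them. The median SE over all shared regions was 0.253. Why these regions lie on chromosome 20 was not tested. A region with no gene within 50 kb, from 53865004 to 53865503, rose from 350 ± 21.1 to 1369 ± 89.2 (log2 1.97, SE 0.10, limma adjusted p = 2.43e-18), and regions starting at 53852065, 53863885 and 53865974 rose by 1.42, 0.80 and 0.69. Beside ZMYND8, which encodes a chromatin reader, the region from 47359040 to 47359539 rose from 532 ± 3.13 to 1440 ± 115 (1.42), and another inside the gene rose by 1.55. The body of NCOA3, a coactivator of nuclear receptors, held a region from 47540342 to 47540841 that rose from 203 ± 42.7 to 590 ± 9.10 (1.57), and a region 31070 bp from the transcription factor gene SALL4 rose by 1.26.

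The number of calls was smaller when a compared library was left out, which leaves 1 library in its group, and when scaled by background depth. Beside the 4377 calls with GDC9545 from all 6 libraries, new limma fits gave totals of 1108 without GDC9545 replicate 2, 1586 without GDC9545 replicate 1, 2417 without DMSO replicate 1 and 2903 without DMSO replicate 2. Scaled by background depth limma called 761 lower and 438 higher regions. Of the 4377 regions, 1188 were still called there and all kept their sign. All but 1 and 2 kept it without GDC9545 replicates 1 and 2. These regions were chosen for their change and the fits reuse the same libraries, so few signs could turn. The planned rank test called 0 regions, with 6185 lower and 5226 higher at an unadjusted p under 0.05 and 197 lower and 48 higher with limma's trend and robust options, so that 4377 is a result of the test added later.

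Peaks present in both DMSO libraries and absent with GDC9545 numbered 6770, and 3030 showed the reverse. The 4 cross-group patterns of the same libraries held 1456 to 5282 regions, and simulations without an effect gave 3875 lost and 2531 gained on average, so that the losses lay above both and the gains inside the first range. The losses lay above the cross-group range in every setting with all 6 libraries, and the gains above it with the 50000 strongest peaks of each library (1348, range 366 to 540). Thinned to the background depth of the shallowest library, which leaves signal over background as it was, the lost regions numbered 3955 and the gained 3249, against 1419 to 3202. Both lay above that range, the gains by little. Leaving out a library asks less of a region, and gave 18011 and 27503 lost without DMSO replicates 1 and 2 and 10880 and 17209 without GDC9545 replicates 1 and 2, with 7539, 5486, 16211 and 14486 gained in the same order. AGR3, a gene of secretory epithelium, held a lost region at genome background, on chromosome 7 from 16880589 to 16881088 (gene body), with a pileup of 69.0 ± 24.0 and 17.8-fold enrichment in DMSO (n = 2). CISH, a cytokine signal inhibitor, lost a region 1185 bp outside the gene on chromosome 3 from 50605054 to 50605553 (155 ± 43.1, 6.18-fold). The remaining lost regions with the highest percentiles were at CASKIN2 (411 ± 115), D2HGDH, CBFA2T3, IL24, TPD52L2 and CAMKK1. Several sit in raised local background, such as 116 ± 24.6 cut sites at CASKIN2, where a peak is lost when it no longer exceeds its surroundings. Gained regions were at PCBD2 (386 ± 26.9 over a local background of 163 ± 1.66), near BMP7, and at CADM2, CYB5A, BAK1, CCDC25, MID1IP1 and CACNA2D1, the last 6 with a mean pileup of at most 34.5.

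**Figure D2:**
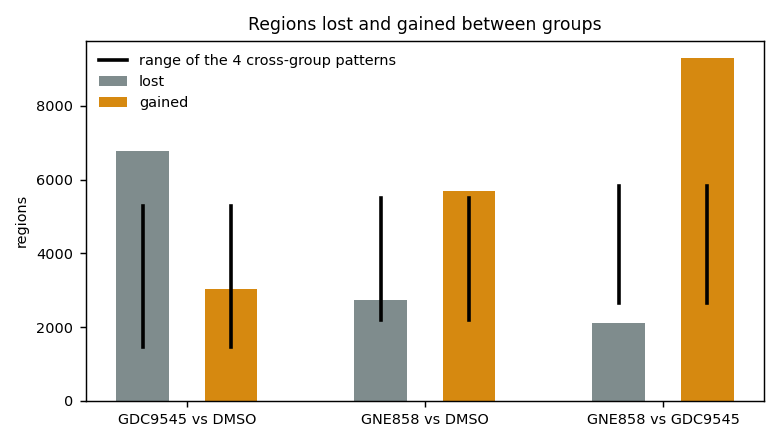
Number of regions lost (grey bars) and gained (orange bars) in each comparison, with black lines for the range of the 4 cross-group patterns made from the same libraries. The 6770 lost with GDC9545 lie above the range of 1456 to 5282, and the 9304 gained with GNE858 relative to GDC9545 lie above 2645 to 5838.

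Among the other lists, estrogen-repressed genes had 13 regions higher and 4 lower with GDC9545 out of 153, with 5 of 14 genes holding a higher region (camera adjusted p = 0.219). The interleukin receptor gene IL1R1 rose by 2.04 (limma adjusted p = 7.05e-05) and EFEMP1 by 0.62 (0.0108), while regions of GATA4 (−2.17, 8.90e-05) and KLF6 (−1.49, 0.00505) fell. Luminal epithelial genes had 19 lower and 3 higher of 295 (camera adjusted p = 0.0113; adjusted p = 0.340 with an estimated correlation), for example −1.30 at GRHL1 and 1.68 at TFAP2C. Growth factor receptor genes had 16 lower and 2 higher of 209 (0.0481; adjusted p = 0.340 with an estimated correlation), with −1.12 at IGF1R, −1.23 at FGFR4, −1.10 at EGFR and −0.60 at IRS1. AP-1 and immediate early genes had 15 lower and 4 higher of 179 (0.286), with −2.13 at EGR3 and 0.79 at FOSB, and other steroid receptor and response genes 14 and 3 of 230 (0.670), with −0.73 at RXRA and 1.58 at ZBTB16. Adjusted over the list alone, the lower and higher regions were 6 and 20 for the estrogen-repressed list, 25 and 3 for the luminal, 20 and 2 for the growth factor receptor, 20 and 4 for the AP-1 and 16 and 3 for the other steroid receptor list. Interferon genes shifted upward by camera (0.0402; adjusted p = 0.340 with an estimated correlation), with 2 of their 119 regions higher, 1 of them at BST2 (0.73), and 1 lower, at MX2 (−0.69), and 0 in either direction adjusted over the list alone by limma (pileup test).

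Basal and myoepithelial genes had 9 regions lower and 3 higher with GDC9545 of 149, cholesterol and fatty acid genes 7 and 2 of 158, growth arrest genes 5 and 4 of 141, unfolded protein response genes 3 and 2 of 106, cell cycle genes 2 and 2 of 143, apoptosis genes 1 and 4 of 144 and mesenchymal genes 1 and 0 of 89. Cholesterol genes included LDLR, the LDL receptor (log2 −0.87, limma adjusted p = 6.21e-05), apoptosis genes BCL2L1 (0.93), cell cycle genes UHRF1 (−1.24), CDK1 (1.01) and CCNE1 (0.38), and growth arrest genes BTG2 (0.56) and TOB1 (−1.09). Markers of immune cells had 2 lower and 1 higher of 49, of neurons 3 and 1 of 107 and of hepatocytes 2 and 0 of 24, and housekeeping genes 1 and 0 of 78. Camera's adjusted p was 0.0550 for the basal list and at least 0.602 for the other lists of this paragraph. Adjusted over the list alone, the basal list had 16 lower and 5 higher regions and each of the others was within 1 region of its count above. For the immune and neuronal markers camera's direction differed in sign from the list's median shift (0.04 and −0.03). With ranks in place of pileups, camera called none of the 18 lists with GDC9545 (smallest adjusted p 0.0853, and 0.613 for estrogen-induced genes). With ranks by −log10 p estrogen-induced genes were lower (camera adjusted p = 1.15e-08; adjusted p = 0.0894 with an estimated correlation), with 42 of 47 genes lower. With the main rule for lost and gained regions, no list was enriched among them in any comparison (smallest adjusted p 0.616, 10000 random gene sets). Estrogen-induced genes held 38 lost regions against 28.1 ± 5.33 in random sets (adjusted p = 0.806). With the 50000 strongest peaks of each library, the estrogen-induced list was called among regions lost with GDC9545.

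**Figure D3:**
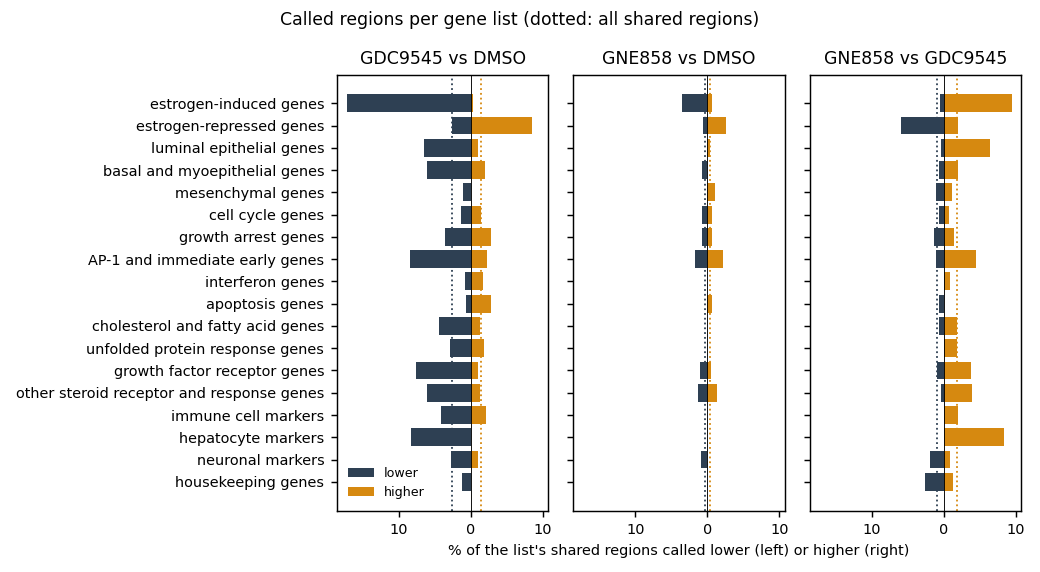
Percentage of each gene list's shared regions called lower (left, dark) or higher (right, orange) in the pileup test, 1 panel per comparison, with dotted lines for all shared regions. Estrogen-induced genes reach 17.2% lower with GDC9545, against 2.63% of all shared regions.

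With GNE858, fewer regions passed the test than with GDC9545, and regions of estrogen-induced genes were among those lowered in the pileup test. This test called 286 regions lower and 368 higher. Of the 435 regions of estrogen-induced genes, 15 fell and 3 rose, and 8 of the 47 genes had a lowered region (26 and 9 regions adjusted over the list alone). GREB1 held 7 of these 15. Its region on chromosome 2 from 11542333 to 11542832 (gene body) went from 246 ± 30.5 in DMSO to 71.2 ± 14.6 with GNE858 (n = 2 each), a log2 change of −1.81 (SE 0.18, limma adjusted p = 1.08e-08), and the one from 11483160 to 11483659 at the end of the gene went from 365 ± 52.1 to 208 ± 2.12 (−0.79, adjusted p = 0.000354). The list fell by camera (adjusted p = 0.0206; adjusted p = 0.528 with an estimated correlation), and this call ended without DMSO replicate 2 (0.161) or without GNE858 replicate 2 (0.117). By ranks, the planned measure, the list had a median shift of 0.0158, with 29 of 47 genes higher and a camera adjusted p of 0.718. The median rank shift was −0.0559 with ranks by −log10 p (adjusted p = 0.909) and −0.0429 without GNE858 replicate 2 (0.978).

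TFF1 and PGR had 1 lowered region each with GNE858. At TFF1, from 42364390 to 42364889 on chromosome 21, the pileup was 81.8 ± 14.0 (log2 −0.87, SE 0.18, limma adjusted p = 0.00704), and at the end of PGR, from 101129558 to 101130057 on chromosome 11, it was 89.0 ± 19.3 (−0.76, adjusted p = 0.0228). The zinc finger gene EGR3 (−1.14, adjusted p = 0.00829) and the amino acid transporter gene SLC7A5 (−0.42, 0.0279) also fell. In contrast, a region in the body of RARA, a retinoic acid receptor gene, on chromosome 17 from 40322226 to 40322725 rose from 340 ± 22.8 to 546 ± 49.2 (0.69, 0.000181), and one near CA12, a carbonic anhydrase gene, rose by 0.84 (0.00178). MYC had 1 of 14 regions lower, at its end on chromosome 8 from 127735921 to 127736420 (621 ± 17.6 to 472 ± 16.2, −0.39, 0.0326). No region of ESR1 (32 tested, smallest adjusted p 0.418), CCND1 (8, 0.148), FOXA1 (5, 0.410) or GATA3 (15, 0.217) passed with GNE858.

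The regions with the smallest adjusted p among those lowered by GNE858 were, besides GREB1, near PARD6B (1429 ± 85.6 to 608 ± 66.9 on chromosome 20 from 50724778, log2 −1.24, limma adjusted p = 8.99e-14), in the bodies of PRSS16 (−1.57), MESD (−1.04) and ARRB1 (−0.95), at the end of GALK1 (−1.41), and 2 regions without a gene, on chromosome 10 from 110408130 (−0.99) and on chromosome 20 from 48076127 (−0.53). PRSS16 encodes a serine protease, MESD a chaperone, ARRB1 beta-arrestin 1 and GALK1 galactokinase. Among raised regions, the smallest adjusted p was at the end of PSMC5, a proteasome subunit gene, on chromosome 17 from 63826601 to 63827100, from 176 ± 10.7 to 824 ± 82.3 (2.24, SE 0.12, adjusted p = 2.27e-16). PREX1, an exchange factor for Rac, had a region in its body on chromosome 20 from 48864663 to 48865162 that rose from 279 ± 24.8 to 657 ± 20.1 (1.25). A region near RGS9 rose to 227 ± 20.1 (adjusted p = 2.25e-09), and one without a gene on chromosome 11 from 69891491 rose from 114 ± 18.3 to 293 ± 8.50. Regions near the muscle transcription factor gene MYOG (1.07), in CHST8 (1.47) and OTUD7B (2.05), and at the end of the collagen gene COL1A1 (1.55) rose as well.

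The number of GNE858 calls moved with libraries and scaling too. New fits gave totals of 256, in place of 654, without DMSO replicate 1, 283 without DMSO replicate 2, 365 and 405 without GNE858 replicates 2 and 1, and 408 and 412 without GDC9545 replicates 1 and 2. Scaled by background depth 9 lower and 19 higher regions were called, and limma without weights gave 129 and 207. The 15 lower regions of estrogen-induced genes were 4 without DMSO replicate 1, 8 without DMSO replicate 2, 5 and 9 without GNE858 replicates 1 and 2, and 2 when scaled by background depth. All 654 kept their sign in all of these fits except 1 without DMSO replicate 1. They were chosen for their change and the fits reuse the same libraries, so few signs could turn. The planned rank test called 0 regions (3090 lower and 3730 higher at an unadjusted p under 0.05, and 0 with limma's trend and robust options).

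Lost regions with GNE858 numbered 2729 and gained ones 5679, beside cross-group patterns of 2197 to 5512 and simulated values of 3397 and 3187. The losses lay inside the cross-group range, but above it with the 50000 strongest peaks (626, range 403 to 544) and below it with all deposited peaks (3975, range 4041 to 7722). The gains lay just above it. They lay inside it with a q of 1e-05 or less (1042, range 166 to 1403), merged intervals (6088, range 2394 to 6095), 50% cover of the window (410, range 111 to 422) and libraries thinned to equal background depth (2921, range 1318 to 2972). Without DMSO replicates 1 and 2 the gains were 13989 and 9742 and the losses 10689 and 16440, and without GNE858 replicates 1 and 2 they were 43218 and 21304 and 9839 and 5594. Lost regions named were at VMP1 (548 ± 72.1 over a local background of 288 ± 19.9), GREB1 (124 ± 16.3 over 41.8 ± 5.63, on chromosome 2 from 11543747 to 11544246), ACOT7, IL6R, PEDS1, ANKRD9, PGR (53.5 ± 7.78 over 11.9 ± 1.52, on chromosome 11 from 101128953 to 101129452) and SPINT2. Gained regions were at PARD6B (864 ± 146 over 387 ± 53.8), TGM2, USP31, TRAM2, MAP3K12 and BCL10, and, in low background, near MINDY4B (91.5 ± 17.7 over 4.34 ± 0.435) and in MLLT10 on chromosome 10 from 21630419 to 21630918 (71.5 ± 0.707 over 3.18 ± 0.00554).

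In the other lists GNE858 changed few regions, and camera called none of them (smallest adjusted p 0.240, cell cycle genes). Estrogen-repressed genes had 4 higher and 1 lower of 153, for example 0.58 at NEDD9 (limma adjusted p = 0.0189). Other steroid receptor and response genes had 3 higher and 3 lower of 230, with a rise from 93.0 ± 2.52 to 197 ± 4.25 at ESR2, which encodes estrogen receptor beta (0.000107), and −0.77 at PER1 (0.0290). AP-1 and immediate early genes had 4 higher and 3 lower of 179, with 0.95 at IER3 (1.50e-05) and 0.60 at CCN2 (0.0452). Growth factor receptor genes had 2 lower and 1 higher of 209, the higher one in IGF1R (0.87, 0.00208). Cell cycle genes had 1 lower, UHRF1 (−1.06), and 1 higher, MYBL2 (0.94), growth arrest genes 1 lower, TOB1 (−0.67), and 1 higher, BTG2 (0.62), apoptosis genes 1 higher, BCL2L1 (0.61), mesenchymal genes 1 higher, basal genes 1 lower, KRT17 (−0.90), luminal genes 1 higher and markers of neurons 1 lower, TUBB3 (−0.50). Interferon, cholesterol, unfolded protein response and housekeeping genes and markers of immune cells and hepatocytes had 0 regions called by limma of 119, 158, 106, 78, 49 and 24 (pileup test). Adjusted over the list alone, the lower and higher regions were 2 and 6 for the estrogen-repressed list, 7 and 9 for other steroid receptors, 3 and 5 for AP-1, 2 and 3 for growth arrest and 2 and 1 for housekeeping genes, and within 1 region of the counts above for the others.

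The compounds were also compared with each other. Against GDC9545, 2050 regions were higher and 1030 lower with GNE858. Of the 2870 regions lowered by GDC9545 (median log2 −0.94), the median with GNE858 was −0.22 (quartiles −0.42 and −0.03), and 1274 of them were higher with GNE858 than with GDC9545. The 1507 regions raised by GDC9545 (median 0.90) had a median of 0.39 with GNE858, and 383 of them were lower than with GDC9545. Because these regions were chosen for their change with GDC9545, part of the gap between the medians comes from the choice.

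Estrogen-induced genes were higher with GNE858 than with GDC9545 at 41 regions and lower at 2, and 25 of 47 genes had a higher region (62 and 8 regions adjusted over the list alone). On pileups at gene ends alone, 21 of 44 genes were higher and 23 lower (camera adjusted p = 0.0643). The median shift there was −0.00308, against −0.0596 over all genes. Relative to DMSO, 32 of the 44 were lower with GDC9545 and 39 with GNE858 at gene ends, with medians of −0.178 and −0.156. Camera gave an adjusted p of 4.31e-10 (limma), with adjusted p = 0.0715 with an estimated correlation and 0.172 by ranks (2.52e-06 with ranks by −log10 p, and 0.141 there with an estimated correlation). At the GREB1 region from 11498496 to 11498995, 477 ± 8.14 in DMSO, the pileup was 135 ± 1.45 with GDC9545 and 513 ± 65.6 with GNE858, a difference of 1.89 on the log2 scale (SE 0.15, adjusted p = 2.31e-12). Differences were 2.59 at PDZK1, 3.08 at HSPB8 (14.2 ± 4.98 against 118 ± 0.0467) and 1.96 at TIPARP. By contrast, TFF1 differed by −0.09 (SE 0.21, adjusted p = 0.903), PGR by −0.08 (SE 0.20, 0.903) and the GREB1 region from 11542333 by 0.64 (SE 0.26, 0.217), so a difference between the compounds was not detected there. No region of TFF1, PGR, FOXA1, GATA3 or CCND1 passed between the compounds, and 4 of 22 of GREB1 and 1 of 32 of ESR1 were higher with GNE858. MYC had 1 of 14 higher and 1 lower.

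**Figure D4:**
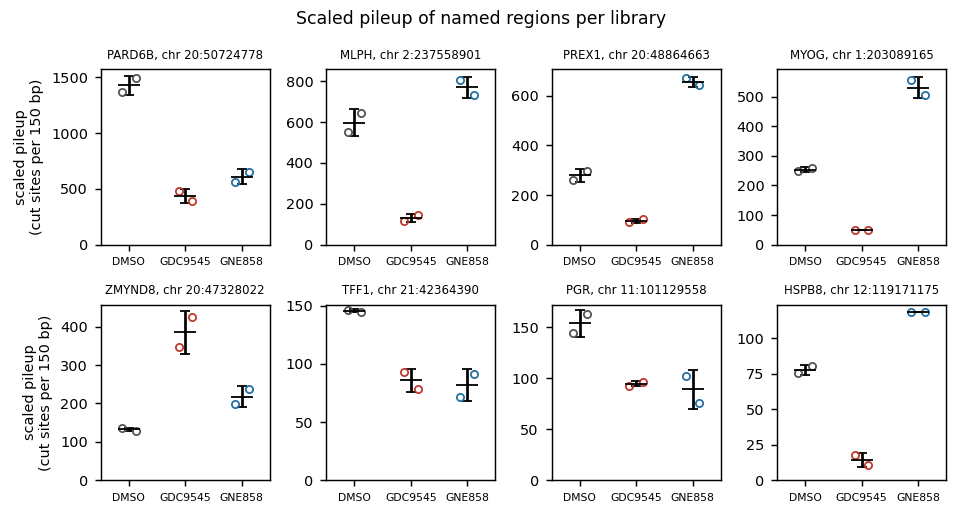
Scaled pileup (cut sites per 150 bp, axis from 0) of 8 named regions in each library (circles), with the group mean and SD (bars, n = 2). TFF1 and PGR are lower with both compounds, MLPH is at 131 with GDC9545 and 771 with GNE858, and at PREX1 and MYOG the GNE858 libraries lie above DMSO and the GDC9545 libraries below it.

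Among regions higher with GNE858 than with GDC9545, the smallest adjusted p values were at PREX1 (96.7 ± 7.60 with GDC9545 and 657 ± 20.1 with GNE858, log2 2.75, SE 0.16, limma adjusted p = 9.70e-16), at a region without a gene on chromosome 20 from 48157961 to 48158460 (72.1 ± 1.88 and 586 ± 16.2, 3.01), near MLPH (131 ± 18.9 and 771 ± 51.7, 2.54) and near MYOG (49.5 ± 0.831 and 530 ± 36.1, 3.41). Lower with GNE858 were the chromosome 20 region from 53865004 (−1.11), the one beside ZMYND8 from 47359040 (−0.96) and 2 in LOC102724250 on chromosome 1, from 629501 (−0.77) and 632502 (−0.91). The last 2 have mean pileups of 7112 or more in every group and lie in a stretch of chromosome 1 that is known to carry a nuclear copy of mitochondrial DNA, so that reads of mitochondrial origin can map there.

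The count of differences moved with the libraries too. New fits gave totals of 731, in place of 3080, without GDC9545 replicate 2, 1060 without GDC9545 replicate 1 and 1832 without GNE858 replicate 1. Limma called 145 lower and 514 higher when scaled by background depth, which moves the median shared region by −0.11 on the log2 scale. The 41 higher regions of estrogen-induced genes were 23 and 20 without GDC9545 replicates 1 and 2 and 18 with that scaling. Limma's rank test called 0 regions (4455 lower and 5781 higher at an unadjusted p under 0.05), with 13 lower and 275 higher by the trend and robust options and 1 and 16 in the 104310 regions called in all 6 libraries.

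Between the compounds, 9304 regions were gained and 2107 lost with GNE858, against cross-group patterns of 2645 to 5838 and simulated values of 3700 and 2587. At equal background depth 4415 were gained and 2340 lost, with cross-group patterns of 1840 to 4263. The losses, below their range at the libraries' own depth, lay above it with the 50000 strongest peaks (989, range 429 to 503) and inside it with a q of 1e-05 or less (341) or 50% cover (95). Without GDC9545 replicates 1 and 2 the gains were 14343 and 21119 and the losses 13186 and 11360, and without GNE858 replicates 1 and 2 they were 50600 and 27358 and 7532 and 3763. Gained regions named were near CACNG4 (278 ± 99.7 over a local background of 30.1 ± 4.57), near WNK1 (126 ± 15.6 over 5.90 ± 0.445), near MPPED1 and in AGR3 (96.5 ± 27.6 over 3.28 ± 0.277). Lost ones were at PARD6B, BMP7, RNASE12 and SPDYE14, each in raised local background.

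Beside the estrogen-induced list, luminal epithelial genes had 19 regions higher and 1 lower of 295 with GNE858 than with GDC9545 (camera adjusted p = 0.0625; adjusted p = 0.501 with an estimated correlation), for example 1.70 at GRHL2 (limma adjusted p = 1.63e-07) and 1.47 at AR (0.00629). Growth factor receptor genes had 8 higher and 2 lower (camera 0.0424; adjusted p = 0.386 with an estimated correlation), with 1.97 at IGF1R and −1.48 at ERBB4. Interferon genes shifted downward (0.0424; adjusted p = 0.386 with an estimated correlation), although their 1 called region, at ISG20, was higher (0.96). Estrogen-repressed genes had 9 lower and 3 higher (0.804), with 3.27 at GATA4 and −0.42 at BCAS1. Other steroid receptor genes had 9 higher and 1 lower (2.19 at ESR2), AP-1 genes 8 and 2 (2.28 at FOSL2, 1.12 at KLF2, −0.79 at FOSB), basal genes 3 and 1, cholesterol genes 3 and 1 (0.62 at LDLR), unfolded protein response genes 2 and 0 (0.79 at XBP1), growth arrest genes 2 and 2, cell cycle genes 1 and 1, mesenchymal genes 1 and 1 and apoptosis genes 0 and 1. Markers of immune cells had 1 higher and 0 lower, of hepatocytes 2 and 0, of neurons 1 and 2, and housekeeping genes 1 and 2, with −0.48 at ACTB. Camera's adjusted p was at least 0.0760 for the lists with no p given here. Adjusted over the list alone, the higher and lower regions were 23 and 3 for the luminal, 13 and 2 for the growth factor receptor, 4 and 12 for the estrogen-repressed, 11 and 1 for the other steroid receptor and 10 and 8 for the AP-1 list, and within 1 region of the counts above for the others.

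The 2 compounds shared 190 lowered regions and 82 raised ones in the pileup test. Independent lists of these lengths would share 7.52 and 5.08, and simulated groups without effects against the same DMSO libraries 85.1 and 84.6. The simulated lists matched the total length over both directions and not the length of each direction. Whether the shared increases exceed what common controls give cannot be told from them. Shared lost regions numbered 1300 (64.1 for independent lists, 902 simulated) and shared gained regions 737 (59.7 and 608). The simulated lists for GDC9545 and GNE858 had other lengths than the observed ones, 3875 and 3397 lost and 2531 and 3187 gained. The simulated overlaps therefore cannot be set directly against the observed ones. The rank shifts of the compounds correlated across regions at r = 0.458, against 0.499 simulated with no effect, with a covariance of 0.0480 against 0.0304. Opposite calls numbered 88, of which 83 were lower with GDC9545 and higher with GNE858, against 13.6 for independent lists and 0.25 in the simulations. Common DMSO libraries move both comparisons the same way, so few opposite calls were bound to arise in those simulations.

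**Figure D5:**
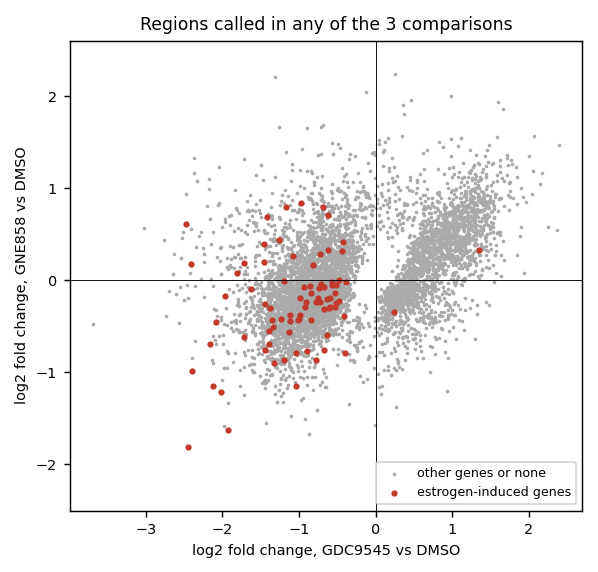
Log2 fold change with GNE858 (vertical axis) against that with GDC9545 (horizontal axis), both relative to DMSO, for the regions called in any of the 3 comparisons (points), with estrogen-induced genes in red. The DMSO libraries are common to both axes. The upper left holds the 83 regions called lower with GDC9545 and higher with GNE858.

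Shares of gene ends were tested as if regions were independent. Gene ends made up 5.26% of the regions lost with GDC9545 and 2.57% of those gained, against 4.14% of cross-group regions (Fisher's exact test across regions, two-sided, p = 0.000477 and 2.89e-05). With GNE858 they made up 5.57% of the lost and 3.59% of the gained regions, against 4.17% (Fisher's exact test, p = 0.00138 and 0.0581; p = 0.0204 for the gained regions at equal background depth). Between the compounds they made up 2.75% of the regions lost and 4.48% of those gained with GNE858, against 4.09% (Fisher's exact test, p = 0.00255 and 0.145; p = 0.0511 for the lost regions at equal background depth). The simulations of the rank test used ranks of pileups in place of fold enrichment and found 0 of 100 changed regions. In the rank test a shift of gene ends relative to other regions was not detected (limma's camera across regions, unadjusted p = 0.332, 0.987 and 0.325). With ranks by −log10 p they lay lower than other regions with GNE858 against DMSO (limma's camera, unadjusted p = 0.0343; 0.188 with an estimated correlation). On pileups they lay lower with GNE858 against DMSO and against GDC9545 (limma's camera, unadjusted p = 7.50e-05 and 0.00440; 0.106 and 0.198 with an estimated correlation). With GDC9545 against DMSO limma's camera gave an unadjusted p of 0.682. In the pileup test 246 of 18488 gene ends were lower and 172 higher with GDC9545, 64 and 22 with GNE858, and 407 and 98 with GNE858 relative to GDC9545. Of 45735 regions in gene bodies 1318 and 642, 90 and 179, and 302 and 972 were called in the same order.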

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

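The tests of depth, of scaling and of chance with common controls, and the pileup test itself, were chosen only after the results were seen.

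The difference between the 2 compounds was itself tested by limma on the pileups, and the regions below passed. Of the shared regions, 2050 were higher and 1030 lower with GNE858 than with GDC9545, and 41 of the higher ones belong to estrogen-induced genes. Log2 differences (GNE858 minus GDC9545) at estrogen-induced genes were 2.59 at PDZK1, 1.89 and 1.47 at the GREB1 regions starting at 11498496 and 11530906, 1.96 at TIPARP, 1.902 at ELOVL2, 1.09 at KCNK5, 3.08 at HSPB8, 1.81 at CA12, 0.81 at SLC7A5, 2.104 at RARA and 0.92 at RAB31.

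Among the other named regions higher with GNE858, the differences were 1.52 at SARS1, 2.17 at OTUD7B, 3.41 at MYOG, 2.54 at MLPH, 2.70 at RHOD, 1.00 at ARRB1, 2.98 at TMEM229B, 1.80 at ADCY9, 1.39 at COL1A1, 1.99 at PSMC5, 3.52 at RGS9, 1.96 at CHST8, 2.01 at NINL, 2.75 at PREX1 and 0.47 at PARD6B. Regions without a gene differed by 1.62 on chromosome 11 from 69891491 and by 1.30 and 3.01 on chromosome 20 from 48076127 and 48157961.

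Lower with GNE858 were the LOC102724250 regions starting at 629501 (−0.77) and 632502 (−0.91), PRSS16 (−1.56), GALK1 (−0.63), the ZMYND8 regions starting at 47328022 (−0.86) and 47359040 (−0.96), NCOA3 (−1.26) and SALL4 (−0.61). Regions without a gene on chromosome 20 differed by −0.64, −0.69, −1.11 and −0.45, starting at 53852065, 53863885, 53865004 and 53865974.

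Lower pileups at estrogen-induced genes with GDC9545 were set against 2 technical explanations. Strong regions are called more often, but random sets matched on mean pileup gave 13.0 lower calls on average, with an upper bound for the test of 20 and a highest value of 28, against 75. A change of copy number or of whole segments would move neighbours as well, and other shared regions within 500 kb had a median log2 change of −0.0682 (quartiles −0.324 and 0.131, 2271 regions), against −0.988 at the lowered regions. The lowered regions were chosen for their fall, so part of this gap comes from the choice. The first comparison argues against strong regions as the explanation. The second argues against a change of whole segments as large as the fall at the lowered regions. An effect of the treatment at estrogen-induced genes may be put as a hypothesis. The count was 32 and 29 without GDC9545 replicates 1 and 2.

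More regions were lost than gained with GDC9545, 6770 against 3030, a ratio of 2.23, and both GDC9545 libraries were the shallowest. With the 50000 strongest peaks of each library, 1373 were lost and 1348 gained. With all libraries thinned to 1 background depth the ratio was 1.22, so that lower depth may account for much of the excess of losses. The tables argue against background depth alone as the cause of every loss, since the lowest number of lost regions over 5 thinning draws was 3905 and the highest cross-group pattern 3216. Signal over background was not matched, and an effect of the compound on the remaining losses stays open.

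A set of 83 regions was called lower with GDC9545 and higher with GNE858. Simulations without effects and with common DMSO libraries gave 0.25 regions in opposite directions on average and at most 1, against 88 in both senses. Common DMSO libraries move both comparisons the same way, so few opposite calls were bound to arise there and this test cannot decide. Independent lists of the observed lengths would give 13.6. The set does not rest on 1 GNE858 library, with 48 without replicate 1 and 68 without replicate 2, although it was 24 and 37 without DMSO replicates 1 and 2 and 45 and 38 without GDC9545 replicates 1 and 2. Scaled by background depth only 2 were called, as the median log2 change with GNE858 went from 0.79 to 0.73 (lower quartile 0.62) while its median SE went from 0.150 to 0.273. The calls ended through the larger error and not through a smaller change. That scaling moved the median shared region by only −0.0591 for GNE858 against DMSO. A change of 0.79 could therefore not fall far, and this test cannot decide whether scaling matters. Opposite effects of the compounds at these regions may be a hypothesis.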

How the results depend on the processing

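Chosen only after results were seen were equal background depth, the pileup test with its scaling by background depth, its fit without weights and its fit of 4 libraries, and the crossed replicate numbers. The recalibrated dispersion of the simulations and the naming of regions by the pileup test were also chosen then. The other alternatives to the planned tests were fixed before the data were examined.

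Counts of lost and gained regions fell with stricter calls, which leave fewer regions to count. With a q of 1e-05 or less they were 1886 and 602 for GDC9545 against DMSO, 460 and 1042 for GNE858 against DMSO and 341 and 2219 for GNE858 against GDC9545. With the 50000 strongest peaks of each library they were 1373 and 1348, 626 and 1098, and 989 and 1546, and with 50% cover of the window 829 and 208, 167 and 410, and 95 and 1224. At equal background depth 3955 regions were lost with GDC9545, 1757 lost and 2921 gained with GNE858, and 4415 gained between the compounds. When absence meant no peak of q 0.01 or less, 4096 were lost with GNE858. Shared losses of the compounds were 2038 with all deposited peaks, 169 at the stricter q, 2248 with that absence, 280 with the strongest peaks, 55 with 50% cover and 749 at equal background depth, and shared gains 102, 372 and 29 at the stricter q, with the strongest peaks and with 50% cover.

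Leaving out each library in turn asks less of a lost or gained region, so counts rose by construction. They ran from 10880 to 27503 lost and 5486 to 16211 gained with GDC9545, 5594 to 16440 and 9742 to 43218 with GNE858, and 3763 to 13186 and 14343 to 50600 between the compounds. Shared losses ran from 1606 to 11356 and shared gains from 1098 to 3110, and the correlation of the rank shifts from 0.367 to 0.611. A lone library was assumed to vary like the other groups.

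The rank test by limma stayed at 0 calls without each library (0 to 0 in each comparison), where all 6 libraries gave 6185 and 5226, 3090 and 3730, and 4455 and 5781 regions at an unadjusted p under 0.05. It called 245 and 288 regions with trend and robust options for GDC9545 against DMSO and between the compounds, and 17 between the compounds in regions called in all libraries. The pileup test called 1199, 28 and 659 regions in the 3 comparisons scaled by background depth. For GNE858 against DMSO it called 336 without weights and 418 in a fit of 4 libraries. Without each library its calls ran from 1108 to 4934, 256 to 412 and 731 to 3355. Lowered regions of estrogen-induced genes ran from 29 to 77 with GDC9545 and 4 to 10 with GNE858, higher ones between the compounds from 20 to 42, and opposite regions from 24 to 68. Scaled by background depth these were 27, 2, 18 and 2, and without weights 8 were lower with GNE858 and 45 were opposite. With a replicate block they were 10 with GNE858, and in a fit of 4 libraries 10. Of 161 results at named regions, 77 were labelled the same and 84 weaker when scaled by background depth, and 143 and 18 with a replicate block. These results need not all be calls, as FOXA1 and GATA3 were named by rule and had no called region in any comparison. A result without a call may count as the same. No result was labelled as turned in direction under any setting. Regions named because their groups do not overlap were bound to keep their direction when a library was left out.

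Numbers did not pair the libraries, with correlations of replicate differences of −0.027, −0.021 and −0.115 between the groups. With the number as a block the rank test called 0, 0 and 0 regions and the pileup test 3716, 478 and 2486, and with crossed numbers 3344 between the compounds. For lost and gained regions no paired analysis was run, because no test of presence was planned and there was no fit to block.

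For gene lists, ranks by −log10 p gave 2 calls for GDC9545 and 2 between the compounds, and gene ends only gave 1 between the compounds. On pileups, gene ends only gave 2 for GNE858 and 0 between the compounds, and the replicate block 1 between the compounds. Without each library the ranks gave 0 to 0, 0 to 1 and 0 to 3 calls and the pileups 1 to 2, 0 to 2 and 1 to 4. With an estimated correlation 0 of these list calls held. For estrogen-induced genes with GDC9545 on pileups, camera's adjusted p with an estimated correlation was 0.0387 in the main fit and 0.191 with the replicate block. The estimated correlations were −0.0168 and −0.0127, under the preset 0.01, so they do not account for the larger p. Among regions lost with GDC9545, 1 list was called with the 50000 strongest peaks, the estrogen-induced genes, with 19 regions against 6.76. The shift of gene ends relative to other regions turned to −0.0123 (ranks by −log10 p) and −0.00808 (pileups) for GDC9545, and to −0.0312 and −0.0870 for GNE858, and was −0.0773 between the compounds on pileups. Camera's p for the last 2 pileup values was 7.50e-05 and 0.00440, and with an estimated correlation 0.106 and 0.198. The cause was not tested for these changes.

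Sequence motifs and their alternatives were not run, as no genome sequence was used here. Depth limits the weak regions: simulated 2-fold changes were found in 45, 56 and 48 of 100 regions, so a region without a call may have changed. For GNE858 against DMSO, 28 of the 654 calls held under both scalings.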

Other observations

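The regions of this part were chosen only after their values were seen. Of the 83 regions lower with GDC9545 and higher with GNE858, 40 lay in gene bodies, 39 between genes and 4 at gene ends, they were assigned to 67 genes, and 3 belonged to estrogen-induced genes. Their median log2 change was −1.37 with GDC9545 and 0.79 with GNE858. Besides PREX1, RGS9 and MYOG, the regions with the smallest adjusted p for GNE858 were near SLCO3A1, a transporter gene (110 ± 38.3 in DMSO, 19.5 ± 2.54 with GDC9545 and 260 ± 22.7 with GNE858, mean ± SD, n = 2 each), in RIMS4 (204 ± 19.3, 44.1 ± 14.4 and 403 ± 2.96), near SLC2A1, a glucose transporter gene (45.8 ± 10.3, 18.7 ± 3.58 and 147 ± 3.18), and near JARID2, a partner of the Polycomb complex (174 ± 8.75, 89.6 ± 16.2 and 351 ± 21.7). Another 5 regions showed the reverse, with medians of 0.34 and −0.28.

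Chromosome 20 had the highest share of called shared regions in each comparison, 6.26% for GDC9545 against DMSO, 1.45% for GNE858 against DMSO and 4.75% between the compounds, at a median pileup of 73.7. Chromosome 19, at a median pileup of 92.8, had 3.91%, 0.511% and 3.42%. A chromosome's median pileup does not show the pileups of its called regions. The contrast therefore cannot tell whether signal level explains the shares, and copy number was not tested here.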
